A study of Mus musculus with 6 samples.

How the data were processed

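RNA of full-grown mouse oocytes was turned into libraries with a Smart-seq2 protocol, in which cDNA is primed with oligo(dT) and amplified before tagmentation, per the labels' protocols. Poly(A)-primed cDNA favours mRNAs whose tails can be primed, so an altered tail length could change capture as well as abundance. The reads were trimmed with Trim Galore 0.6.7, aligned with STAR 2.7.10a and counted with featureCounts 2.0.2 on mm10, and DESeq2 is listed without a version, per the submitters' processing notes. The annotation release and the strand setting are not given in the sources used here. The deposited values are raw counts per gene, per the file headers, for 55291 gene symbols with exon coordinates, in 5 library columns. Every column matched a labelled sample by name. Of the gene symbols, 53180 matched a single gene of GENCODE M21, 52831 of them with identical chromosome, start and end, and identifiers, gene types and 3' UTR lengths came from that annotation.

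Groups and replicate numbers came from the sample titles. The series text speaks of zygotes and 2-cell embryos while the titles of these samples name full-grown oocytes; the titles were followed. Total counts ran from 3785574 to 26770521 per library, so 1 count was worth 0.0374 to 0.264 CPM and the floor of 3 counts lay between 0.112 and 0.792 CPM. No pair of the libraries other than WT 2 agreed within sampling noise: a chi-square of the counts over its degrees of freedom was between 19.4 and 136 for genes with 20 or more counts in the pair, the lowest for KO 2 and KO 3. All were counted as separate samples.

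The main test was edgeR 4.0.16 (R 4.3.3), quasi-likelihood with robust=TRUE, TMM factors, filterByExpr and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. Gene lists, 20 in all, were tested with limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01, for lists of 5 or more tested members, and again with an estimated correlation and with fry. DESeq2 1.42.0 and limma-voom were alternatives. The other alternatives were DESeq2 size factors, library size alone and upper-quartile factors, no filter on low counts, a mean of at least 5 CPM, predicted, pseudogene and mitochondrial genes left out, robust=FALSE, thresholds of 0.01 and 0.1, thinning to the smallest library, removal of each library's trend on gene length, a replicate block, and leaving out each library. Predicted and pseudogene entries were left out by the form of their names. Annotated pseudogenes with other names, such as Vcp-rs, stayed in, and protein-coding genes with predicted names, such as Gm4737, were dropped. Shares of counts were compared with exact permutation tests, with nuclear protein-coding genes as another denominator. Tests, gene lists, alternatives and the naming rule were fixed before the data were examined.

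Genes were named by a rule: Pan2 and Pan3; among genes that passed, with all KO libraries on one side of the WT libraries, at least 5 CPM in the higher group and no predicted, clone-based or pseudogene-suffix name, the 10 highest and 10 lowest log2 fold changes and the 5 lowest p-values each way; and per list the 2 members with the lowest p that rose and the 2 that fell, or the 1 with the lowest p where none passed. Some list members are left out of the text. A gene whose group had 0 counts was given a bound from 3 counts over that group, set against the summed counts of the other group, each divided by the group's summed effective library size, so it can differ from a ratio of mean CPM, and one with 1 to 3 counts an exact 95% binomial interval of the count ratio.

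After WT 2 had been seen to depart from the other libraries, the fit without WT 2, planned as an alternative, was taken through all the same steps as a comparison of its own, WT 1 against the 3 KO libraries, and these steps were also run on the genes of the first 90 Mb of chromosome 16 and on these together with 5 Mb windows in which WT 2 correlated at 0.8 or more with the others. The 4 libraries other than WT 2 were also split in other ways, and WT 1 and each KO library were set against the same pairs of KO libraries. To test for counts placed in other coordinates, the exon coverage expected from the other libraries was moved by offsets of up to 3 Mb in steps of 50 bases in 10 Mb windows and recounted on the gene models; the same search was run with values permuted among genes. The offset search and shares used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures matplotlib 3.10.9.

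The steps were tested on simulated data with known changes drawn from the real means, library sizes and fitted dispersions. Changes were placed only in genes above a minimum mean count, so recovery at rarer transcripts was not tested. The lone WT library was given the spread fitted to the KO libraries, so whether it varies like them was not tested either. For WT 1 against the KO libraries (17044 genes) 54% of 4-fold changes and 4% of 2-fold changes were recovered, with 7 false calls; for the region of chromosome 16 (419 genes) 76.7% and 10%; and for all 5 libraries (15934 genes) 0% of either. Changes of 2-fold were thus mostly missed in every comparison, and with all 5 libraries those of 4-fold were missed as well. Smaller changes were not simulated.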

Results

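RNA sequencing was carried out on full-grown mouse oocytes, the large germinal-vesicle cells that hold the stored maternal mRNA, from wild-type (WT) females and from Pan2 knockout (KO) females. PAN2 is the catalytic subunit of the PAN2-PAN3 deadenylase, which shortens the poly(A) tails of mRNAs, and the question was how its loss alters the oocyte transcriptome. The labels name 6 samples in both groups together, of which 5 libraries, 2 WT and 3 KO, were analysed; the WT replicate numbered 3 was not analysed here. The gene counts summed to 23485093 in WT 1, 3785574 in WT 2, and 12038990, 23359636 and 26770521 in KO 1, KO 2 and KO 3. The labels do not say whether replicates came from separate females, so the p-values measure the spread between these libraries, which may be technical.

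Pan2 itself (ENSMUSG00000005682.9, chromosome 10, 128303335 to 128321358 in mm10, plus strand) had counts in every library, though those in WT 2 need not come from this gene. Its normalized level was 77.6 CPM (the usual depth-scaled count, with TMM factors) in WT 1 and 44.6, 11.9 and 34 CPM in KO 1, KO 2 and KO 3 (30.2 ± 16.7 CPM, SD, n = 3). The KO libraries all lay below WT 1, with a log2 fold change of -1.37 (SE 0.53), which did not pass the test (edgeR adjusted p = 0.301). The comparison planned before the data were examined was of all labelled samples, and was run here with both WT libraries. Its log2 fold change was -1.22 (SE 1.41, edgeR adjusted p = 0.958), with 68.4 CPM in WT 2, whose counts on this chromosome did not follow the other libraries. Under the other settings planned beforehand that value ran from -3.61 with upper-quartile factors to -0.63 without WT 1, with adjusted p from 0.247 to 1. Against WT 1 Pan2 passed without a filter on low counts and without KO 1 (log2 fold change -1.74), and in none of its other alternatives. Without KO 1 the spread came from KO 2 and KO 3 alone, the closest pair of libraries. A large part of all genes passed in that fit, as did many genes when KO 1 was set against the same pair. Calls gained without KO 1, here and below, are therefore weak evidence of an effect of genotype. The counts cover whole genes and the labels do not give the deleted part, so transcripts that lack only some exons would still be counted. Pan3, the regulatory partner of PAN2, stood at 240 CPM in WT 1 and 176 ± 20.6 CPM (SD, n = 3) in the KO libraries, a log2 fold change of -0.44 (SE 0.30) that did not pass (adjusted p = 0.579).

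Transcripts of oocyte-specific genes were abundant in 4 of the 5 libraries, while WT 2 had few or no counts at these genes. Gdf9, which encodes a growth factor secreted by oocytes, reached 4327 CPM in WT 1 and 3598 ± 374 CPM (SD, n = 3) in KO oocytes, and Zp3, a zona pellucida gene, 3062 and 2892 ± 467 CPM. Both had 0 counts in WT 2, as did Bmp15, Zp2 and the oocyte linker histone gene H1f8. This was not particular to oocyte genes: Actb, the cytoplasmic beta-actin gene, had 2 counts in WT 2 and 128 to 214 CPM in the other libraries. Across genes, log2 CPM in WT 2 correlated with that in the other libraries at 0.333 to 0.34, whereas the other 4 correlated with one another at 0.98 to 0.995. Chromosome by chromosome, WT 2 stayed between 0.029 and 0.179 on chromosomes 1 to 19 and X other than 16, and the lowest value of the other libraries was 0.941. On the first 90 Mb of chromosome 16 it correlated with them at 0.95 to 0.959. These correlations are across genes, which are not independent replicates.

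**Figure D1:**
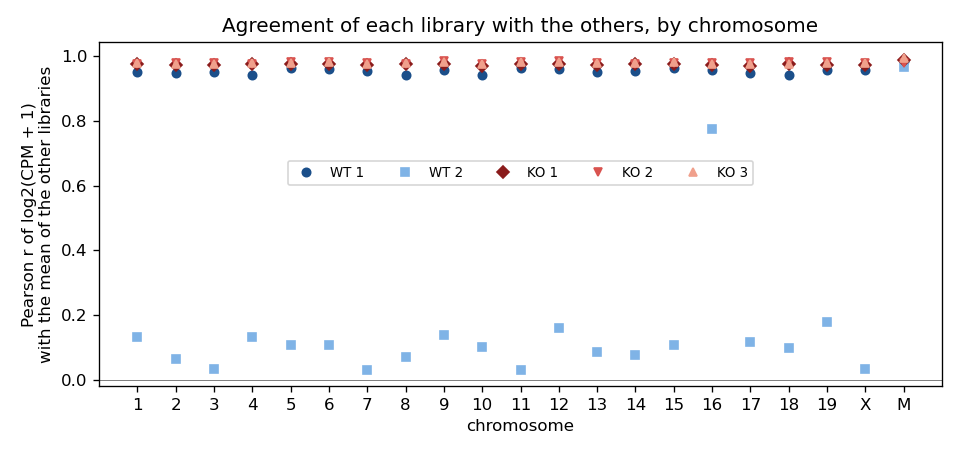
Pearson correlation of log2(CPM + 1) of each library with the mean of the other libraries apart from WT 2 (vertical axis) for the genes of each chromosome (horizontal axis); each symbol is a library. WT 2 lies between 0.029 and 0.179 except on chromosomes 16 and M, while the others lie at 0.941 or higher.

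Some genes were near 0 counts on one side and clearly detected on the other when the KO oocytes were set against WT 1. Tox3, an HMG-box transcriptional coregulator, had 0 counts in WT 1 and 33.8 ± 8.7 CPM (SD, n = 3) in KO oocytes, at least 280-fold higher when the summed counts of the KO libraries, 2157 for this gene, are set against a floor of 3 counts in the WT library, each over its effective library size. Arid5b, which encodes an ARID-domain DNA-binding protein, rose 164-fold, from 1.46 to 240 ± 42 CPM. In the other direction, Bfsp1, the gene for the lens filament protein filensin, fell from 40.3 CPM to 0 counts in every KO library, at least 825-fold lower with 3 counts over the KO group as the floor, and Cdc5l, a component of the spliceosome, fell 54.7-fold, from 147 to 2.76 ± 1.42 CPM. These values come from WT 1 against the 3 KO libraries, which was planned as an alternative with WT 2 left out and was taken as a comparison of its own after WT 2 had been examined, and in which the lone WT library is assumed to vary like the KO libraries.

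In that comparison 344 of 17799 genes passed an adjusted p of 0.05 in edgeR, 235 higher and 109 lower in KO oocytes, all by 2-fold or more. With both WT libraries, in the test planned for all labelled samples, 0 of 16738 genes passed in edgeR. An unadjusted p under 0.05 was seen for 1050, limma-voom called 0 and DESeq2 called 1049 (234 higher, 815 lower). Without KO 1 the count against WT 1 was 4923 genes (2702 higher, 2221 lower), all 344 among them. KO 1 set against the same KO 2 and KO 3 gave 3460 genes. Of the 344 genes, 50 had 0 counts in WT 1 and 9 had 0 counts in all KO libraries.

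Iqcf1, an IQ-motif gene, had 0 counts in WT 1 and 28.4 ± 12.7 CPM (SD, n = 3) in KO oocytes, at least 206-fold higher (adjusted p = 0.00112). Raet1d, a ligand gene of the NKG2D receptor, was at least 105-fold higher, at 12.9 ± 1.22 CPM; it overlaps exons of Raet1e, so its counts are uncertain. The beta-defensin gene Defb8, the olfactory receptor gene Olfr878, the potassium channel gene Kcnh8, the T-cell receptor segment Trav13-3 and Nfam1 also had 0 counts in WT 1 and were at least 66.7-, 55-, 45.8-, 43.2- and 42.3-fold higher, again from the summed counts. With limma-voom the calls of Iqcf1, Defb8, Olfr878, Kcnh8, Trav13-3 and Nfam1 were lost, with adjusted p from 0.0715 to 0.121. Sh3rf2, a RING-finger ubiquitin ligase gene, and Extl1, an exostosin-like glycosyltransferase gene, had 2 counts each in WT 1. Their count ratios were 411 (95% counting interval 114 to 3400) and 228 (63.1 to 1888). Floors and intervals cover counting error only, since amplified reads are not independent molecules.

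Genes that fell included Lrrc31, a leucine-rich repeat gene, from 41.6 to 0.496 ± 0.126 CPM (SD, n = 3), a log2 fold change of -6.38 (SE 0.42, adjusted p = 0.000408). Agbl2, a tubulin deglutamylase gene, fell from 32.4 to 0.854 ± 0.245 CPM, and Vcp-rs, a processed pseudogene, from 15.8 to 0.555 ± 0.154 CPM. The homeobox gene Pknox2 had 12.2 CPM in WT 1 and 0 counts in the KO libraries, at least 251-fold lower. Chl1, a cell adhesion gene, had 2 counts in the KO group, a count ratio of 173 (95% counting interval 47.1 to 1446). The cytokine gene Il11, the butyrophilin gene Btn1a1 and the olfactory receptor genes Olfr995 and Olfr1257 fell by log2 values of -5.99, -6.62, -6.51 and -5.57; Btn1a1 did not pass in DESeq2 (adjusted p = 0.578). Lrrc31 overlaps exons of Gm15462, Cdc5l those of B230354K17Rik and Eif2ak3 those of Gm43292. Whether strand was used in counting is not given in the sources used here, so reads of such pairs cannot be assigned with certainty, and reads of the pseudogene Vcp-rs may be shared with its parent gene.

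**Figure D2:**
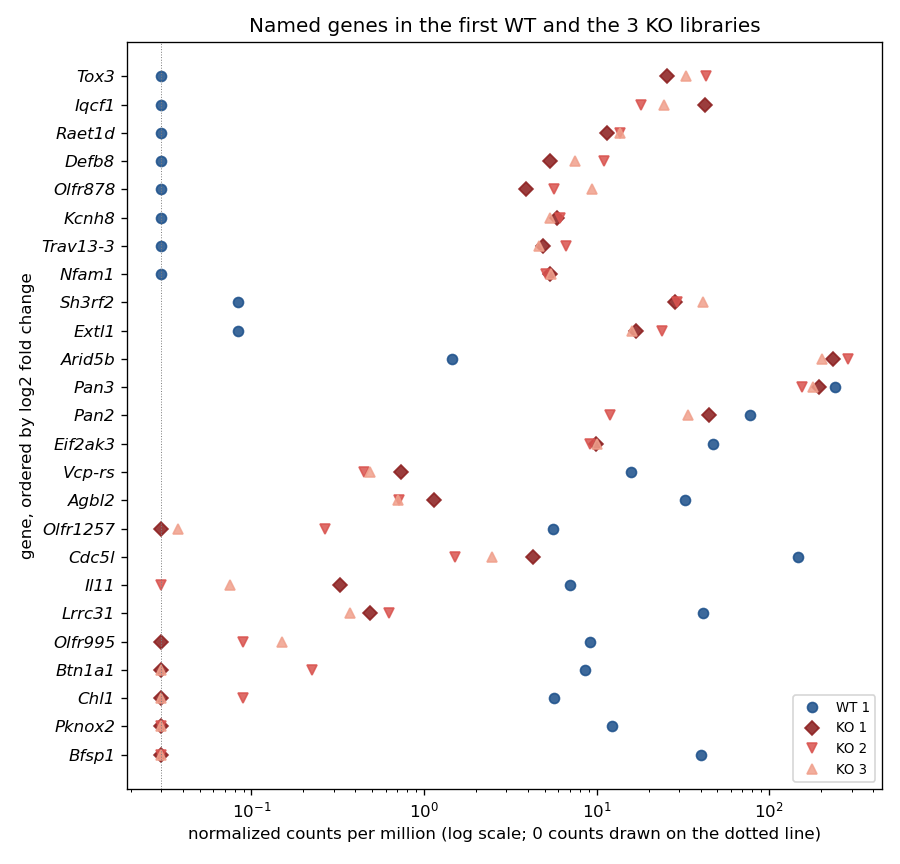
Normalized CPM (horizontal log axis, 0 counts on the dotted line) of the genes named by fold change or p-value, with Pan2, Pan3 and Eif2ak3, in WT 1 and the 3 KO libraries; each symbol is a library. Tox3 rises from 0 counts to 33.8 CPM on average and Bfsp1 falls from 40.3 CPM to 0 counts, while Pan3 is at 240 CPM in WT 1 and 176 CPM on average in the KO libraries.

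Gene lists fixed before the data were examined showed few members that passed. None of the 25 deadenylase genes, 40 mRNA decay genes or 41 genes of polyadenylation and tail binding rose or fell against WT 1 in edgeR, over all genes or adjusted over the list alone, with median log2 fold changes of 0.02, -0.13 and -0.22. The members nearest to passing were Btg3, an antiproliferative gene of the BTG/Tob family, at 0.0836 CPM in WT 1 and 1.59 ± 0.557 CPM (SD, n = 3) in KO oocytes (edgeR adjusted p = 0.0837), Dis3l, a cytoplasmic exosome ribonuclease gene, at 190 and 85.3 ± 6 CPM (adjusted p = 0.0836), and Pabpn1l, an embryonic poly(A)-binding protein gene, at 615 and 364 ± 39.5 CPM (adjusted p = 0.301). Btg3, with 2 counts in WT 1, had a count ratio of 20.6 (95% counting interval 5.58 to 173) and overlaps exons of Cxadr. Btg3 and Dis3l passed with DESeq2 (adjusted p = 0.0495 and 0.0282), without a filter on low counts (0.0118 and 0.0329) and without KO 1 (0.000156 and 9.94e-10), and Pabpn1l without KO 1 (1.56e-05). Over the other alternatives the adjusted p reached 0.283 for Btg3, 0.356 for Dis3l and 0.911 for Pabpn1l. In camera these lists had adjusted p of 0.712, 0.397 and 0.397.

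Cytosolic ribosomal protein genes were lower as a group in the fit of KO oocytes against WT 1, 72 of 82 having a negative log2 fold change, with a median of -0.34 (camera adjusted p = 0.0142; adjusted p = 0.823 with an estimated correlation). The difference lay in KO 2 and KO 3: the group's share of all counts was 2.64% in WT 1, 2.91% in KO 1, 1.69% in KO 2 and 1.66% in KO 3. The ribosomal RNA gene CT010467.1, a sign of how much ribosomal RNA was carried into a library, was also lower in KO 2 and KO 3, with 2.47% of counts in WT 1, 1.49% in KO 1, 0.554% in KO 2 and 0.565% in KO 3. WT 1 and KO 1 set against KO 2 and KO 3 gave 344 genes in edgeR. The median of the list was -0.71 without KO 1, -0.24 without KO 2 and -0.21 without KO 3, with adjusted p of 8.16e-09, 0.185 and 0.367. Only Rpl29 passed alone, over all genes and adjusted over the list alone, and it rose from 21.9 to 96.2 ± 15.6 CPM (SD, n = 3); reads of ribosomal protein genes can be shared with their processed pseudogenes. The 81 nuclear genes of oxidative phosphorylation had a median of -0.30 and did not pass (camera adjusted p = 0.0923), but the list passed at a mean of at least 5 CPM (median -0.33, adjusted p = 0.005) and without KO 1 (median -0.55, adjusted p = 4.89e-05), and had an adjusted p of 0.823 with an estimated correlation. The 8 mitochondrially encoded genes tested did not pass, with a median of -0.20 (adjusted p = 0.397).

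Maternal mRNAs known to be translated on maturation had a median log2 fold change of 0.31, with 18 of 21 above 0, and the list did not pass (camera adjusted p = 0.154; 0.027 without KO 1; 0.823 with an estimated correlation). Plat, the tissue plasminogen activator gene, stood at 619 CPM in WT 1 and 1741 ± 639 CPM (SD, n = 3) in KO oocytes (edgeR adjusted p = 0.176). The 51 genes of oocyte identity and maternal effect had a median of -0.04, the 37 of mRNA storage -0.04 and the 64 of the meiotic cell cycle 0.15, with 0 members passing in each. Khdc3, a gene of the subcortical maternal complex, was at 342 and 163 ± 10.4 CPM (adjusted p = 0.108), and Aurkc, the germ-cell Aurora kinase gene, at 104 and 240 ± 13.3 CPM (adjusted p = 0.113). All 3 passed with DESeq2, with adjusted p of 0.0235 for Plat, 0.0451 for Khdc3 and 0.0157 for Aurkc, and without KO 1 (2.06e-18, 6.29e-08 and 4e-09). Plat also passed without a filter (0.0104), and the highest adjusted p of the alternatives were 0.387, 0.496 and 0.488.

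Of 33 genes of the integrated stress and unfolded protein responses, Eif2ak3 fell and the other 32 did not pass. Eif2ak3 encodes PERK, the kinase that phosphorylates eIF2 alpha under endoplasmic reticulum stress, and went from 47.4 to 9.72 ± 0.495 CPM (SD, n = 3), a log2 fold change of -2.29 (SE 0.32, edgeR adjusted p = 0.00583). The list itself did not pass (camera adjusted p = 0.673). No member passed over all genes among 26 replication-dependent histone genes (3 fell when adjusted over the list alone), 37 proteasome genes, 48 translation factor genes, 27 genes of p53 targets and apoptosis and 54 chromatin genes, with medians of -0.28, 0.12, -0.02, -0.29 and -0.20 and camera adjusted p of 0.111, 0.673, 0.753, 0.35 and 0.111. The chromatin list passed without KO 1 (median -0.44, adjusted p = 0.00895; 0.823 with an estimated correlation and all 3 KO libraries).

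Markers of other cells took small shares of the counts in WT 1 and the KO libraries. The highest granulosa or cumulus marker still reached 276 CPM in WT 1 and 339 CPM on average in KO oocytes. The counts assigned to the blood list and to the theca, stromal and endothelial list were a larger share in WT 2. The blood list took 0.00172% of counts in WT 1, 0.0259% in WT 2 and 0.00419 ± 0.000699% (SD, n = 3) in KO oocytes, and the theca, stromal and endothelial list 0.0039%, 0.0246% and 0.00472 ± 0.000398%. Ptprc, the gene of the leukocyte antigen CD45, stood at 62.6 CPM (237 counts) in WT 2 and at 0 to 0.0856 CPM in the other libraries. Pecam1, an endothelial adhesion gene, stood at 202 CPM (765 counts) in WT 2 and at 14.9 to 26.2 CPM in the others. Both lie on chromosomes where WT 2 did not follow the other libraries, 1 and 11, so these counts need not come from the named genes. The blood gene Hba-a1 had 0 counts in every library, and the stromal gene Col1a1 had 0 counts in WT 2. The granulosa and cumulus list took 0.0577% of counts in WT 1, 0.0215% in WT 2 and 0.0725 ± 0.00541% (SD, n = 3) in KO oocytes, with Cyp19a1, the aromatase gene, at 13.9 CPM in WT 1 and 38.8 ± 6.31 CPM in KO oocytes (edgeR adjusted p = 0.0967). Cyp19a1 passed with DESeq2 (adjusted p = 0.0084), without a filter (0.0258) and without KO 1 (2.4e-08), and its adjusted p reached 0.384 over the other alternatives. Against WT 1 the granulosa and cumulus list had a median log2 fold change of 0.47 over 14 genes, the theca, stromal and endothelial list 0.08 over 12, and transcripts of the 2-cell stage 0.69 over 14, and 0 members of them passed over all genes. Adjusted over the list alone, 1 granulosa marker rose. The median of the 2-cell list was also 0.69 with its 2 members at 0 counts in a group set to their bounds. The camera adjusted p of these lists were 0.197, 0.712 and 0.111. Only 4 blood markers could be tested, too few for camera, and 1 of them rose when adjusted over the list alone.

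With both WT libraries 5 lists passed camera, and 0 did with an estimated correlation, their adjusted p all being 0.916. The 8 mitochondrially encoded genes were lower, with a median log2 fold change of -2.70 (camera adjusted p = 2.51e-06). This difference came from WT 2. Their share of counts was 0.344% in WT 1, 3.29% in WT 2 and 0.281% on average in KO libraries, and the median against WT 1 alone was -0.20. Translationally activated maternal mRNAs (median 1.18), oocyte identity and maternal-effect genes (0.93), cytosolic ribosomal protein genes (0.66) and nuclear oxidative phosphorylation genes (0.64) were placed higher than the other genes by camera, with adjusted p from 0.0269 to 0.029. The median of all genes in that fit was 0.68, so the ribosomal and oxidative phosphorylation medians lay below it, while their means of 0.46 and 0.57 lay above the mean of all genes, 0.30. WT 2 had 0.231% of its counts in the oocyte identity list against 6.49% in WT 1. Against WT 1 alone the oocyte identity, ribosomal and oxidative phosphorylation medians had the opposite sign.

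**Figure D3:**
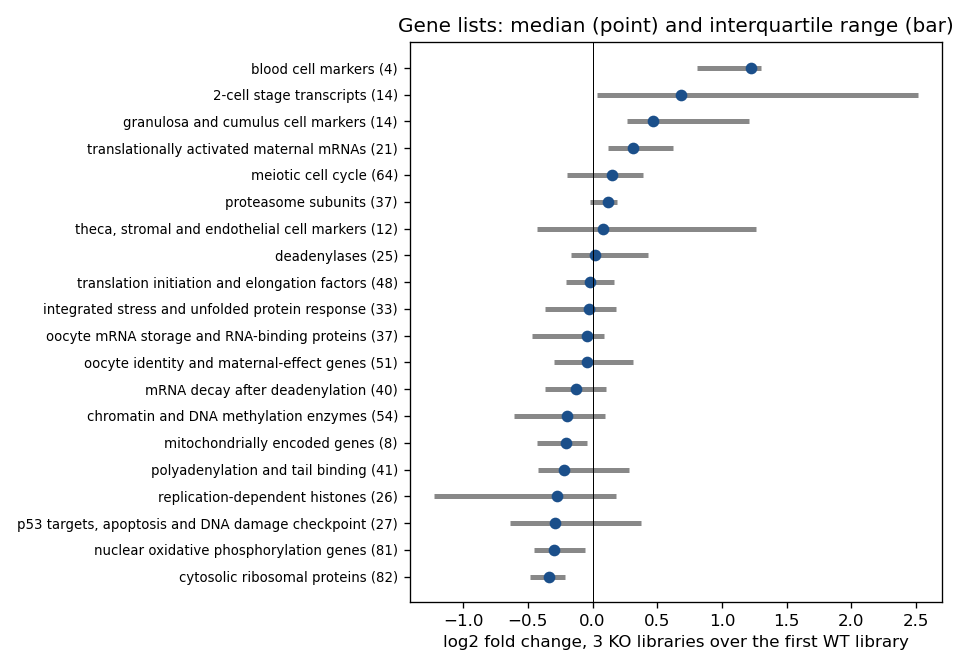
Median (point) and interquartile range (bar) of the log2 fold change of the 3 KO libraries over WT 1 (horizontal axis) for each gene list, with the number of members tested in brackets. Cytosolic ribosomal protein genes have the lowest median, -0.34.

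The first 90 Mb of chromosome 16, where WT 2 broadly followed the other libraries, allowed both WT libraries to be set against the 3 KO libraries. Single genes could still depart there: Rpl24 had 1773 counts in WT 2 and 0 to 6 in the others. Of 438 genes tested there, 7 passed in edgeR, 3 higher and 4 lower. Slc12a8, a solute carrier gene (chromosome 16, 33517328 to 33664135 in mm10), fell from 4910 ± 571 (SD, n = 2) to 768 ± 145 (SD, n = 3) CPM of the region's counts (log2 fold change -2.67, SE 0.29, adjusted p = 0.00325). Nfkbiz, an inducible regulator of NF-kB target genes, fell from 4732 ± 200 to 1367 ± 257 (adjusted p = 0.0109). Mb21d2 rose from 235 ± 118 to 1546 ± 198 (adjusted p = 0.0109) and Jam2, a junctional adhesion molecule gene, from 372 ± 138 to 1908 ± 636 (adjusted p = 0.0246). Jam2 lies in a 5 Mb window where WT 2 correlated with the other libraries at only 0.574, over 5 genes, so its call is less certain. The olfactory receptor gene Olfr206 had 0 counts in both WT libraries and was at least 63.9-fold higher in KO oocytes with 3 counts over the WT group as the floor. The deadenylase-list gene Btg3 had 2 and 0 counts in the WT libraries and 66.9 ± 23.2 CPM of the region's counts (SD, n = 3) in KO oocytes (edgeR adjusted p = 0.0661), and passed with DESeq2 (0.00376), without a filter (0.00118), at a mean of at least 5 CPM (0.0366), with predicted genes left out (0.0409) and without WT 1 (0.00978) or WT 2 (0.0328). Its adjusted p was highest, 0.831, with a replicate block and the length trend removed. The other 2 called genes, Ndufs5-ps and Gm4737, a pseudogene and a gene with a predicted name outside the naming rule, were lower by log2 values of -2.71 and -4.79. Without KO 3 the count was 0, and without WT 1 it was 57.

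**Figure D4:**
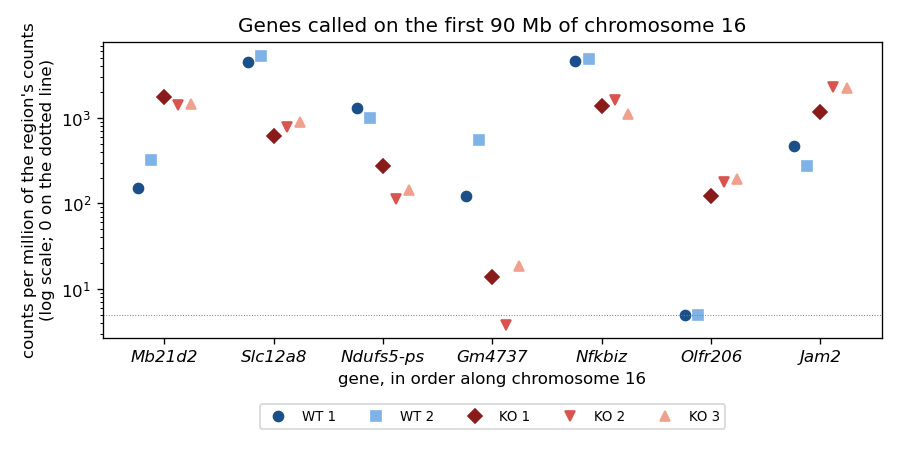
CPM within the region's counts (vertical log axis, 0 on the dotted line) of the 7 genes called on the first 90 Mb of chromosome 16, in order of position; each symbol is a library. At each gene both WT libraries lie on the same side of the 3 KO libraries, as at Slc12a8, 4910 against 768 on average.

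The share of counts taken by the 10 most abundant genes was 7.24% in WT 1, 9.69% in WT 2 and 5.51 ± 0.196% (SD, n = 3) in KO libraries. With 2 libraries against 3 an exact two-sided permutation test cannot give a p below 0.2, and this share, that of pseudogenes and those of granulosa markers and 2-cell transcripts had exact p = 0.2, the smallest possible (0.55 after Benjamini-Hochberg adjustment over the 11 shares compared). Mitochondrially encoded genes took 0.344% in WT 1, 3.29% in WT 2 and 0.281 ± 0.0984% in KO libraries (exact permutation p = 0.4). Across genes, the log2 fold change against WT 1 had a Spearman correlation of -0.01 with gene length and 0.04 with mean log2 CPM, and with both WT libraries -0.11 and 0.06. With both WT libraries the correlation with mean log2 CPM was 0.25 at a mean of at least 5 CPM and 0.27 without WT 1, and that with gene length -0.04 and -0.05.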

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

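The settings for both WT libraries were planned for all labelled samples, the fit without WT 2 among them. The further settings on WT 1 alone and those on chromosome 16 were chosen after the data were seen. Of the 344 genes called against WT 1, all 344 were called with DESeq2 size factors, 337 with DESeq2, 219 with limma-voom and 334 with the gene length trend removed, and 344 of 344 kept their sign in each of these. The cause of the changes below was not tested. Stricter filters and fewer gene types left fewer genes to test, which covers only part of the lower counts. Of the genes called against WT 1, 202 were still tested at a mean of at least 5 CPM. Without predicted, pseudogene and mitochondrial genes 213 were still tested. Both numbers exceed those that stayed called.

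With both WT libraries the count of 0 became 1233 (1 higher, 1232 lower) without a filter on low counts and 1049 (234 higher, 815 lower) with DESeq2. Leaving out 1 library gave 0 to 15277 genes (0 to 10914 higher, 0 to 4363 lower), the highest without WT 1 and 344 without WT 2. The 5 gene lists that passed camera became 0 with an estimated correlation, 0 with fry, 8 at a mean of at least 5 CPM and 1 to 13 with 1 library left out, 13 without WT 1 and 1 without WT 2. The median log2 fold change of all genes was 0.68, and 0.17 with upper-quartile factors. The log2 fold change of Pan2, -1.22 with both WT libraries, stayed negative and did not pass in the 18 planned settings. Its size moved, to -3.61 with upper-quartile factors, -3.14 with the length trend removed and -3.02 with the replicate block as well. It ran from -1.63 to -0.63 with 1 library left out. All but the fit without WT 2 rest in part on the counts of WT 2, which need not come from Pan2.

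Against WT 1 the 344 genes became 868 (574 higher, 294 lower) without a filter, 126 (92 and 34) at a mean of at least 5 CPM, 163 (113 and 50) without predicted, pseudogene and mitochondrial genes, 672 (519 and 153) with DESeq2, 231 (125 and 106) with limma-voom, 131 (81 and 50) at an adjusted p of 0.01 and 545 (372 and 173) at 0.1. Leaving out a KO library gave 425 to 4923 genes (285 to 2702 higher, 140 to 2221 lower), 4923 without KO 1. The 1 list that passed became 0 with an estimated correlation, 0 with fry, 2 at a mean of at least 5 CPM and 0 to 4 with a KO library left out. List members that did not pass against WT 1 passed with DESeq2 besides those already named: Eif3j1 (adjusted p = 0.0179), C1qb (0.0268), Sirt1 (0.0271) and Trp53bp1 (0.0393), with adjusted p up to 0.424, 0.352, 0.373 and 0.522 in the other settings. Pan2 passed without a filter (log2 fold change -1.37, edgeR adjusted p = 0.0085), and ranged from -1.74 to -0.99 with a KO library left out, passing without KO 1. The direction of the camera test turned for proteasome genes with the length trend removed (median 0.09), for translation factors without KO 3 (median 0.03) and for p53 targets at a mean of at least 5 CPM (median 0.14), none passing.

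On chromosome 16 the 7 genes became 22 (8 higher, 14 lower) without a filter, 14 (5 and 9) with DESeq2, 9 (5 and 4) at a mean of at least 5 CPM, 7 (5 and 2) without predicted and pseudogene names, 2 (1 and 1) at an adjusted p of 0.01 with 5 higher at 0.1, and 13 (7 and 6) with the further windows. Leaving out 1 library gave 0 to 57 genes (0 to 28 higher, 0 to 29 lower), 0 without KO 3, 14 without WT 2 and 57 without WT 1. With 1 library left out the log2 fold change of Psmd2 ran from -0.44 to 0.15 (0.15 without WT 2) and that of Trp63 from -0.56 to 0.15 (0.15 without WT 1), neither passing where it turned.

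The labels do not say that replicate numbers pair the samples, and only 2 pairs were analysed. Deviations from the group means on chromosome 16 correlated at -0.05 and -0.1 within pairs. The deviations of the 2 WT libraries mirror each other, so each of these values is the negative of a value across pairs. They are weak evidence on pairing. With a replicate block the count was 0 for both WT libraries and 0 on chromosome 16 (0 higher, 0 lower). With the block 9 lists passed camera at the preset correlation, and the estimated correlation was not run with it. With the replicate block and the length trend removed the counts were 19 (19 lower) and 0. With the libraries of each comparison thinned to the smallest of them, edgeR called 235 genes (158 higher, 77 lower) of 15806 tested against WT 1 at 12038990 counts, the total of KO 1, 8 on chromosome 16 at 297701 counts, and 0 with both WT libraries at 3785574 counts, the total of WT 2 (575 at an unadjusted p under 0.05).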

Other observations

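The tests of shared offsets, of gene-level correlations with permuted values, of chromosome 16, of pseudogenes and of the second WT library at the genes called, and the splits of libraries 2 against 2, were chosen after the results they bear on had been seen.

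When 5 Mb windows in which WT 2 followed the other libraries were added to the first 90 Mb of chromosome 16, 6 further genes passed, and they were named after their values were seen. The beta-defensin gene Defb8 on chromosome 8 had 0 counts in both WT libraries and 229 ± 80.1 (SD, n = 3) CPM of these regions' counts in KO oocytes. It starts at base 19445769, near the end of its window, and in the next window WT 2 correlated with the others at only 0.128. The 0 counts of Defb8 in WT 2 are therefore less certain. Csmd1, a gene of a large membrane protein, stood at 52.8 ± 34 (SD, n = 2) and 324 ± 47.5 (edgeR adjusted p = 0.0413), and Apod, the apolipoprotein D gene on chromosome 16 itself, at 19 ± 1.96 and 113 ± 11.5 (adjusted p = 0.0449). Gm45410 on chromosome 8 stood at 185 ± 22.8 and 1168 ± 642 (adjusted p = 0.0413). The processed pseudogenes Gm15459 and Gm15772 on chromosome 5 fell, from 4214 ± 556 to 233 ± 48.8 and from 3397 ± 1007 to 369 ± 144.

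Counts assigned in WT 2 to the leukocyte gene Ptprc and the endothelial gene Pecam1 were 62.6 and 202 CPM, above the other libraries. WT 2 departed from the other libraries on most chromosomes, those of both these genes included. Lower depth does not account for it, since the other libraries thinned to its total still had a median correlation of 0.982, nor, as the whole cause, does RNA of another cell type or a failed library, since over all genes of chromosome 16 it correlated with the mean of the others at 0.927 (0.774 over the genes above a log2 CPM of 1). A candidate explanation is that its reads were counted in other coordinates than the gene models: moving the expected coverage by the best offset per window raised the median gene-level correlation over 254 windows from -0.137 to 0.506, short of the 0.6 set beforehand. The best of many offsets raises a correlation without any shift, and with values permuted among genes the same search raised this median from -0.411 to -0.023; best offsets agreed within 5 kb in 62 of 232 pairs of neighbouring windows, and in 0 of 240 with permuted values. The departure also changed with position. In 5 Mb windows of chromosome 8 WT 2 correlated with the others at 0.942 at the start and 0.128 from base 20000001. Chromosome 2 gave 0.074 at its start, and chromosome 16 gave 0.163 to 0.185 near its end. From base 70000001 of chromosome 8 the best offsets were 2521800 to 2531300 bases. On chromosome 7 they ran from -2033400 to 2315150. The changes along chromosomes 8 and 16 argue against RNA of other cells as the main cause there. No biological explanation other than another cell type was tested, and some RNA of other cells in WT 2 stays open.

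The genes that differ between WT 1 and the KO libraries were few within 10 Mb of Pan2, 1 of 135 tested, which argues against a chromosome segment carried over from the targeted cells, and 334 of 344 calls stayed in place after the gene length trend was removed. The share of genes called near Pan2 was no higher than elsewhere. This bears only on the source of most calls, and a carried-over segment that altered few genes stays open. A deviation of the WT 1 library alone is weakly argued against on the first 90 Mb of chromosome 16. At 7 of 8 genes called there, WT 2 lay beyond all KO libraries on the side of WT 1. Chance would give 25% if WT 2 varied like a KO library. It departed more, correlating there with the others at 0.95 to 0.959 while they correlated with one another at 0.983 or more. Chance may thus give a higher share, which was not measured. Outside that region a deviation of WT 1 alone stays open. Whether a lone library calls as many genes whatever the library stays open: against the same 2 KO libraries, KO 1 called 3460 genes and WT 1 4923, whereas KO 2 called 5 against 425 and KO 3 called 2 against 498, and each KO library against the other 3 gave 0 genes in edgeR (139 to 627 at an unadjusted p under 0.05; 344 and 2369 for WT 1), with WT 1 in the spread and 4 splits too few for a share under 0.05. A strain or donor variant against the reference may contribute: pseudogenes, which differ between strains, were over-represented among the calls, with a common odds ratio of 2.02 (95% interval 1.43 to 2.85) over strata of abundance. An effect of the loss of PAN2 stays open beside it, since background strain and genotype cannot be separated with the labels at hand.

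The 4 libraries other than WT 2 can be split 2 against 2 in 3 ways. WT 1 with KO 1 against KO 2 and KO 3 called 344 of 16208 genes (158 and 186 in the 2 directions, 3791 at an unadjusted p under 0.05), a number that happens to equal the count against WT 1, and the other 2 splits called 0 in edgeR (131 and 263 at an unadjusted p under 0.05), which points to a structure of the samples that crosses the groups.

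Fold changes against WT 1 had a Spearman correlation of -0.06 with 3' UTR length over 13466 genes. Each KO library against the other KO libraries gave -0.04, 0.05 and 0.01, so the value lay outside their range by less than the range itself, and an action of PAN2 loss by 3' UTR length can neither be seen nor excluded here.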
